A study of Capra hircus with 6 samples.

How the data were processed

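RNA sequencing of 6 libraries of goat adipose-derived mesenchymal stem cells was examined, 3 from control cells and 3 from cells that overexpress TAZ. Per the labels' protocols, total RNA was taken up in TRIzol, its integrity was assessed on a Bioanalyzer, and libraries were made with the VAHTS Universal V6 kit. The submitters' processing notes name fastp, a read trimmer, HISAT2, a splice-aware aligner, and HTSeq, a read counter, with no versions. The genome build, the strand setting and the treatment of reads that fit several genes are not given in the sources used here, so no coordinates are reported, and paralogs, pseudogene families and overlapping or antisense genes are uncertain. The authors deposited FPKM values (fragment numbers scaled to the length of the gene and to the total of the library), per the file headers, in 1 table for each group with the same genes in both.

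Each table had 16285 rows. In 23 of them a date stood in place of the gene symbol, and these were kept out of the comparisons. The other 16262 symbols were all found in the RefSeq gene table of assembly ARS1.2, which was used for names only. An FPKM value is a fragment number multiplied by a constant and divided by the gene length and the library total, so the steps between low values give both. Library totals came out at 17483995, 16935698 and 17297033 fragments in control replicates 1, 2 and 3 and at 17035481, 18852822 and 18463453 fragments in TAZ replicates 1, 2 and 3. A length was recovered for 99.99% of the rows that had a value above 0, counting a fragment number as whole, or as a multiple of 0.5 for deep genes, within a distance of 0.02, and 68.4% of them stepped in 0.5 fragments. The recovered fragments in the tables made up 99.84% to 99.87% of the totals. Floors and intervals cover counting error only. Fragment numbers were compared between libraries by chi-square, which per degree of freedom was 9.3 to 14.48 within groups and 97.55 to 119.87 between groups, so no pair of libraries lay within sampling noise.

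The samples were grouped by their titles. Genes were kept at 1 FPKM or more in at least 3 of the 6 libraries, which left 10750. Values were taken as log2(FPKM + 1) with no further scaling, and limma 3.58.1 in R 4.3.3 (moderated test, empirical Bayes with a mean-variance trend) compared TAZ overexpression with control, two-sided, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. The labels do not say that replicates came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical. Groups of 3 were not searched for outlying libraries.

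There were 35 gene lists for an adipose stromal cell under adipogenic differentiation with TAZ overexpressed and for other cell types that a stromal culture can hold. The lists were YAP/TAZ-TEAD targets, Hippo components, pro- and anti-adipogenic factors, adipocyte and thermogenic markers, fatty acid synthesis and oxidation, cholesterol synthesis, TNF and NF-kB response, TNF receptor components, interferon response, collagens, matrix crosslinking and proteolysis, contractile genes, TGF-beta response, Wnt signalling, osteogenic and chondrogenic markers, stromal markers, G2/M, S phase, p53 response, unfolded protein response, heat shock, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, immediate early genes, mitochondrial transcripts, and endothelial, leukocyte, pericyte, epithelial and skeletal muscle markers. The 27 lists with at least 5 kept members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. This called 10 lists, 6 up and 4 down, and with a correlation estimated for each list 2 calls held, interferon response and glycolysis and hypoxia. A call lost with an estimated correlation need not mean that members varied together, as the closing section shows. Members are counted by the test over all genes and again adjusted over the list alone.

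Genes named in the text were taken from a rule. WWTR1 came first, then the 10 genes that rose and the 10 that fell most among genes past the threshold with a mean of 2 FPKM or more in the higher group, no overlap between groups and a symbol other than a LOC number. The 4 members of each list with the lowest adjusted p and the leading member in the less frequent direction followed, and then a set of markers whatever their p. The groups, the main tests, the 35 lists, the naming rule and the alternatives below were fixed before the data were examined, and the closing section says which further alternatives, tests of explanations and gene groups were chosen later.

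The alternatives were pseudocounts of 0.1 and 0.5, no filter, a stricter filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, rescaling without the top 50 genes, no mean-variance trend, robust empirical Bayes, the replicate number as a block, leaving out each library, an adjusted p under 0.01, limma's treat test against 1.2-fold, and for the lists an estimated correlation, fry, and camera on ranks. The test was tried on simulated data made from the real levels and depths of the TAZ against control comparison, with 200 genes changed, of which 67, 67 and 64 changed 1.5-, 2- and 4-fold were among the 10654 tested. It recovered 86.6% of changes of 1.5-fold and 100% of changes of 2-fold and 4-fold, with 11 false calls among 200 calls. Every simulated gene was given the same spread between replicates (squared coefficient of variation 0.00683). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading, depth recovery and figures.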

Results

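Messenger RNA levels were measured in goat (Capra hircus) adipose-derived mesenchymal stem cells, the stromal cells of fat tissue from which fat cells can be formed. All 6 libraries are labelled as coming from cells under adipogenic differentiation. The control group holds 3 libraries of wild-type genotype, and the other holds 3 libraries of cells that overexpress TAZ, a transcriptional coactivator of the Hippo pathway that is encoded by WWTR1. The study's stated question was how TAZ affects the formation of fat cells. Its title also names the cytokine TNF-α, but no sample label mentions a cytokine treatment. The FPKM tables hold values from 16935698 to 18852822 fragments per library, as recovered from the steps of the low values. At the median length of the tested genes, 1 FPKM stood for 52.5 fragments. Group values below are mean FPKM ± SD with n = 3 libraries in each group, and log2 fold changes are on the log2(FPKM + 1) scale, TAZ overexpression minus control, which understates the change of low genes. Counts of genes changed at least 2-fold or 4-fold use that scale. Values given as times as high or times the control level are ratios of mean FPKM with nothing added, and so are larger for low genes.

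WWTR1, the overexpressed gene, was 2.99 times as high in the TAZ libraries as in the controls. It stood at 30.2, 29.9 and 35.9 FPKM in control replicates 1, 2 and 3, and at 84.6, 118.1 and 84.2 FPKM in TAZ replicates 1, 2 and 3. The group values were 32.0 ± 3.38 and 95.7 ± 19.5 FPKM (log2 fold change 1.54, SE 0.13, limma adjusted p = 6.91e-07). YAP1, which encodes the paralog of TAZ, did not pass the test at 27.2 ± 1.54 against 30.0 ± 2.56 FPKM (adjusted p = 0.268). The WWTR1 row cannot separate transcripts of the introduced construct from those of the cell's own gene.

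Genes of the antiviral interferon response led the rises. MX2, which encodes a dynamin-like antiviral GTPase, rose from 0.526 ± 0.102 to 546 ± 13.1 FPKM (log2 fold change 8.49, SE 0.086, limma adjusted p = 6.1e-16). ISG15, a ubiquitin-like modifier, rose from 5.25 ± 0.488 to 885 ± 107 FPKM, and RSAD2, which encodes viperin, from 0.0983 ± 0.0517 to 127 ± 4.96 FPKM. IL6, an inflammatory cytokine, rose from 1.03 ± 0.0667 to 144 ± 45.3 FPKM. MX1, CMPK2, IFIT2, IFI44L, IFIT3 and the chemokine gene CCL5 completed the 10 largest rises, with log2 fold changes of 5.76, 5.40, 5.25, 5.19, 5.19 and 5.17. Among the 10 largest falls, PRSS35, a serine protease family member, went from 30.8 ± 5.16 to 2.01 ± 0.828 FPKM (log2 fold change -3.42, SE 0.18, adjusted p = 5.84e-09). ID1, an inhibitor of basic helix-loop-helix transcription factors, fell from 382 ± 82.6 to 59.2 ± 10.96 FPKM (log2 fold change -2.66, SE 0.15, adjusted p = 1.95e-08). The small leucine-rich proteoglycan genes ASPN and OGN fell from 73.7 ± 21.5 to 11.05 ± 3.89 FPKM and from 45.9 ± 12.7 to 8.47 ± 2.19 FPKM. EEF1A2, PMCH, MXRA8, ANKH, CCDC3 and NRP1 also fell, with log2 fold changes of -2.95, -2.95, -2.09, -2.04, -2.03 and -1.99.

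Of 10750 genes tested, 4074 (37.9%) changed at an adjusted p under 0.05, of which 1693 were higher and 2381 lower in the TAZ libraries. A list with a like share of called members does not stand out by its counts. The share of higher genes among those called was 41.6%. Scaling by the median ratio of the libraries instead turned the balance, with 2001 genes higher and 1821 lower, a share of 52.4%. Most changes were small, and 88.1% of the called genes moved by less than 2-fold. Of the 486 genes that changed at least 2-fold, 379 were higher and 107 lower, and 128 were at least 4-fold higher against 9 at least 4-fold lower. With a pseudocount of 0.1, 231 genes were at least 2-fold lower in place of 107, and with the stricter filter 66 were. A fit of the recovered fragments with limma's voom gave 252 at least 2-fold lower, and 756 changed at least 2-fold in place of 486. The values of the 2 groups did not overlap for 5201 genes (48.4%), where chance gives 10% for 3 libraries against 3. Correlations of log2 values across genes ran from 0.9925 to 0.9956 within groups and from 0.9412 to 0.951 between groups, and the first principal component, which separated the groups, held 86% of the variance.

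**Figure D1:**
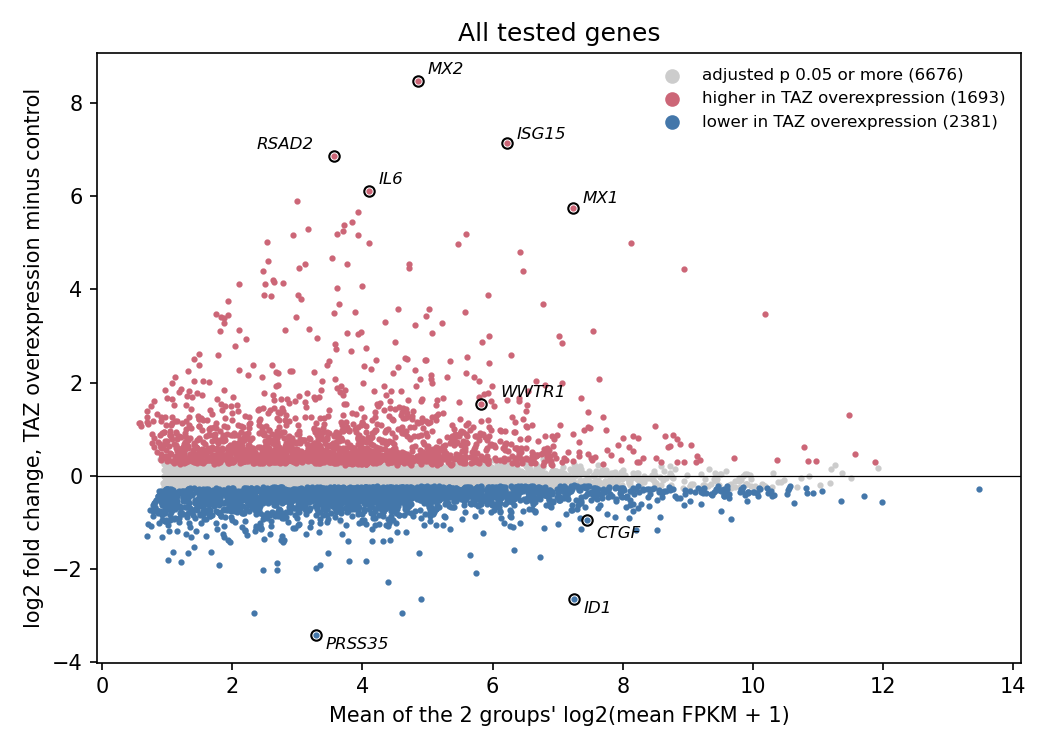
Log2 fold change of FPKM + 1 (vertical axis, TAZ overexpression minus control, 3 libraries each) against the mean log2 level of the groups (horizontal axis, log2 of mean FPKM + 1) for the 10750 tested genes, 1 point per gene. Red points are the 1693 genes called higher and blue points the 2381 called lower at an adjusted p under 0.05, grey points are the other tested genes, and circles mark genes named in the text, from MX2 at 8.49 to PRSS35 at -3.42.

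All 33 tested members of the interferon response list rose, and none fell (33 of 33 also adjusted over the list alone). The median log2 fold change of the list was 4.12, and camera with its preset correlation gave an adjusted p of 2.62e-52, against an adjusted p = 0.0146 with an estimated correlation. MX1 rose from 19.5 ± 0.907 to 1105 ± 38.7 FPKM, and IFIT3 from 6.96 ± 0.701 to 290.1 ± 25.02 FPKM. Of the 30 tested members of the TNF and NF-kB response list, 28 rose, 0 fell and 2 did not pass (28 rose and 1 fell adjusted over the list alone). The list's median was 1.66, with a camera adjusted p of 3.7e-23 that was lost at an adjusted p = 0.202 with an estimated correlation, and 1 fell without control replicate 2. ICAM1, an adhesion molecule for leukocytes, rose from 2.48 ± 0.363 to 43.9 ± 2.11 FPKM, and SOD2, the mitochondrial superoxide dismutase, from 29.5 ± 4.69 to 388 ± 44.5 FPKM. NFKBIA, the inhibitor that NF-kB itself induces, rose from 39.0 ± 17.0 to 105.0 ± 16.9 FPKM, and TNF from 0.368 ± 0.142 to 1.63 ± 0.738 FPKM (log2 fold change 0.91, SE 0.16, limma adjusted p = 0.00068). RELA, which encodes an NF-kB subunit, did not pass at 58.8 ± 2.75 against 51.3 ± 2.35 FPKM (adjusted p = 0.0814). Among the TNF receptor signalling components 6 of 19 rose and 0 fell (5 and 0 adjusted over the list alone), the list was not called (camera adjusted p = 0.0836), and leaving out control replicate 3, TAZ replicate 2 or TAZ replicate 3 left 3 that rose, while 1 fell without control replicate 1 or TAZ replicate 1. It was called up without control replicate 1 (adjusted p = 0.0471), with camera on ranks (0.0455) and with fry (0.0115), but not with an estimated correlation (0.423). CASP8, an initiator caspase, was 2.04 times as high, and CFLAR and TAB2 were 1.56 and 1.39 times as high. The receptor gene TNFRSF1A was 1.19 times as high (adjusted p = 0.03), a call that was lost without control replicate 1 or 3 or without any 1 of the 3 TAZ libraries, at adjusted p-values from 0.0586 to 0.116. MX1 and MX2, and the IFIT genes, have close paralogs, and how reads shared between copies were counted is not given in the sources used here. CCL2 was not analysed here.

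**Figure D2:**
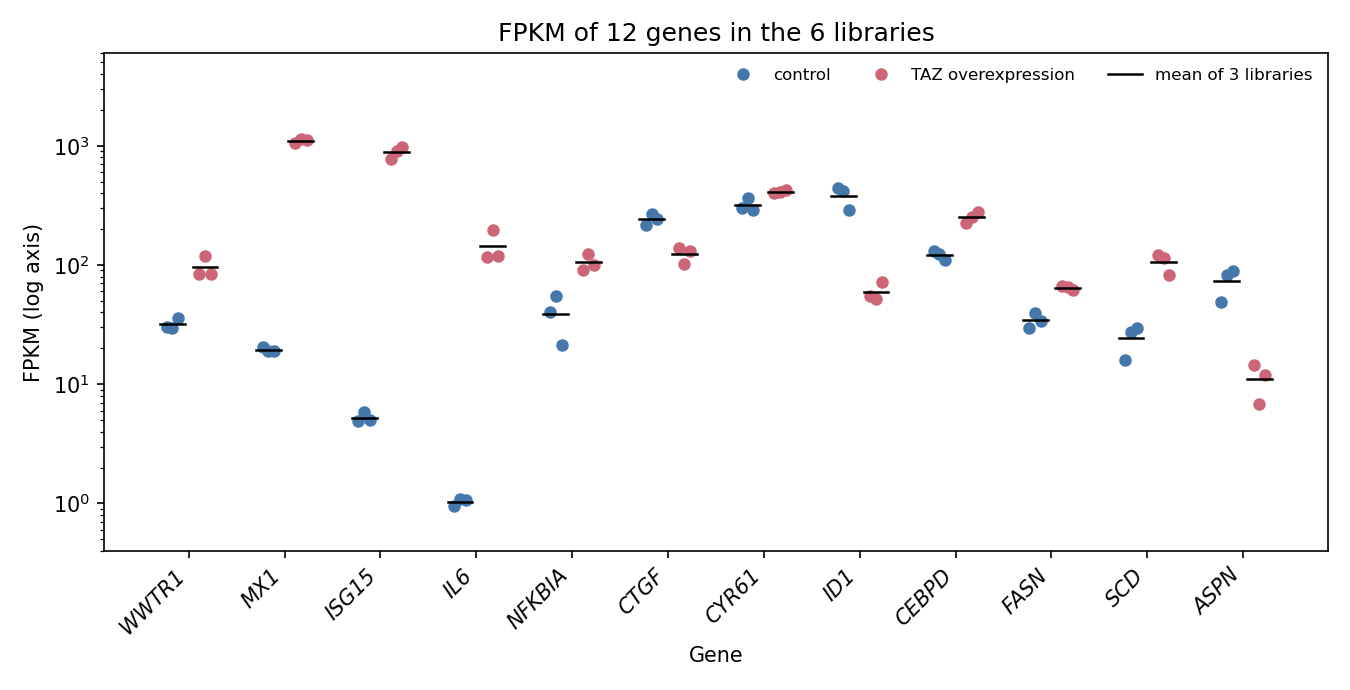
FPKM (vertical log axis) of 12 genes (horizontal axis) in each of the 3 control libraries (blue points) and 3 TAZ libraries (red points), with black bars at the group means. MX1 lay at 19.5 FPKM on average in the controls and at 1105 in the TAZ libraries, while CTGF went from 241 to 125 and CYR61 from 319.5 to 413.

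The canonical target genes of YAP and TAZ moved in both directions. Of 24 tested members of the list of YAP/TAZ-TEAD targets, 8 rose, 8 fell and 8 did not pass (8 and 9 adjusted over the list alone). CTGF (also CCN2), a matricellular growth factor and one of the best known TEAD targets, fell from 241 ± 25.3 to 125 ± 19.7 FPKM (log2 fold change -0.95, SE 0.12, limma adjusted p = 3.2e-05). CYR61 (also CCN1) rose from 319.5 ± 42.0 to 413 ± 12.2 FPKM (log2 fold change 0.38, SE 0.096, adjusted p = 0.00788). IGFBP3, an IGF-binding protein gene, rose from 10.7 ± 3.49 to 95.4 ± 22.3 FPKM, THBS1 from 298 ± 40.0 to 538.5 ± 71.3 FPKM, and NUAK2 from 1.48 ± 0.166 to 3.16 ± 0.515 FPKM. ANKRD1 was below the filter at 0.495 ± 0.341 against 0.499 ± 0.224 FPKM (adjusted p = 0.954 with no filter). The list was not called (camera adjusted p = 0.578). Its median log2 fold change was -0.038, its mean 0.11, and camera's direction was up, so these differ in sign. The number of members that fell was 5 without control replicate 1 or TAZ replicate 3, and 4 with no filter on low genes. Of 27 tested Hippo pathway components, 3 rose and 6 fell (3 and 5 adjusted over the list alone), and camera's adjusted p was 0.776 with a median of 0.024 and a mean of -0.011. These calls made up no larger a share than the 37.9% over all tested genes. WWC2 was 1.71 times as high, WWC1 fell to 0.691 times and AMOTL2 to 0.801 times the control level, and FRMD6 was 1.31 times as high. The 6 falls became 3 without control replicate 1, TAZ replicate 1 or TAZ replicate 3, and 3 under median-ratio scaling or rescaling without the top 50 genes. The call of AMOTL2 was lost without TAZ replicate 2 (adjusted p = 0.0501), and that of FRMD6 without control replicate 2 or TAZ replicate 1 (adjusted p = 0.0541 and 0.0612).

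PPARG and several marker genes of the mature fat cell stayed near 0 in both groups. PPARG, the master regulator of fat cell formation, stood at 0.058 ± 0.0189 FPKM in the controls and 0.0834 ± 0.0741 in the TAZ libraries, from 9 and 14 fragments in all. ADIPOQ, which encodes adiponectin, was at 0.119 ± 0.0368 against 0.124 ± 0.0296 FPKM, PLIN1, a lipid droplet coat protein gene, at 0.1298 ± 0.0353 against 0.0811 ± 0.0374 FPKM, and CD36, a fatty acid transporter gene, at 0.282 ± 0.157 against 0.0942 ± 0.0463 FPKM. LPL, which encodes lipoprotein lipase, had 0 fragments in the controls and 1 in the TAZ libraries, where a count of 0 allows up to 3 fragments per library. These genes were below the filter, and when limma was run with no filter none of them passed (adjusted p = 0.685 for PPARG, 0.916 for ADIPOQ, 0.209 for PLIN1, 0.103 for CD36 and 0.84 for LPL). A difference in LPL was not detectable at this depth. For PPARG the log2 fold change with no filter was 0.032 (SE 0.048), on a scale that compresses values this low. The test therefore does not exclude a 2-fold change of PPARG. CD36 had 133 fragments in the controls and 46 in the TAZ libraries, and its groups did not overlap. On the log2(FPKM + 1) scale, which understates the change of low genes, its log2 fold change was -0.22 (SE 0.084). FABP4 and DLK1 were not analysed here. Of the 13 tested adipocyte markers 3 rose and 1 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.359, median -0.0035, mean 0.077). Fry, which compares with no other genes, called the list up (fry adjusted p = 0.0497). Of these markers 5 rose under median-ratio scaling or rescaling without the top 50 genes, 1 of the 8 tested rose with the stricter filter, and 2 fell without control replicate 3, with no filter or under quantile normalization. LPIN1, a phosphatidate phosphatase gene, was 2.44 times as high, LIPE, hormone-sensitive lipase, 2.10 times and PLIN2, a lipid droplet protein gene of many cell types, 1.36 times, while ADIRF fell to 0.495 times the control level. Not all markers were low, since 13 of the 28 measured passed the filter, and CIDEC, a lipid droplet protein gene chosen here after its values were seen, stood at 18.32 ± 1.306 against 17.84 ± 1.292 FPKM (adjusted p = 0.789). The thermogenic markers had 2 tested members, too few for a list test, of which TMEM26 fell (17.2 ± 2.95 to 11.2 ± 1.38 FPKM) and CIDEA did not pass (2.72 ± 0.465 against 2.26 ± 0.233 FPKM) but fell past the threshold without control replicate 3 (limma adjusted p = 0.0461).

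Pro- and anti-adipogenic factors went both ways. CEBPD rose from 122 ± 11.3 to 251 ± 26.3 FPKM (log2 fold change 1.04, SE 0.099, limma adjusted p = 3.01e-06), CEBPB from 57.2 ± 9.62 to 111 ± 13.96 FPKM, and the lipogenic regulator SREBF1 from 18.4 ± 4.95 to 41.1 ± 2.85 FPKM. KLF4 was 1.87 times as high. CEBPA, which acts with PPARG, fell from 1.87 ± 0.0523 to 0.961 ± 0.0887 FPKM, and EBF1 fell to 0.486 times the control level. Of 16 tested pro-adipogenic transcription factors 6 rose and 3 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.158). It was called with no filter (adjusted p = 0.0441) and with the stricter filter (adjusted p = 0.0114), but not with an estimated correlation (adjusted p = 0.39). Fry, which compares with no other genes, called it up (fry adjusted p = 0.01). Among 20 anti-adipogenic factors 6 rose and 10 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.458). Fry called this list down (fry adjusted p = 0.00735). WNT5A, a noncanonical Wnt ligand, rose from 55.5 ± 7.69 to 146 ± 15.0 FPKM, and CTNNB1, which encodes beta-catenin, was 1.65 times as high. WNT6, a low gene, rose from 0.305 ± 0.0949 to 1.295 ± 0.202 FPKM (log2 fold change 0.81). GATA2, which represses fat cell formation, fell to 0.302 times the control level.

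Many genes for making fatty acids and sterols rose. Of 22 tested genes of fatty acid synthesis and desaturation, 13 rose and 0 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.38 and a camera adjusted p of 0.000222, which was lost at an adjusted p = 0.375 with an estimated correlation. Without control replicate 1, control replicate 3 or TAZ replicate 2, 1 fell. FADS2, the delta-6 desaturase, rose from 12.3 ± 3.16 to 72.8 ± 0.560 FPKM (log2 fold change 2.50, SE 0.14, limma adjusted p = 1.01e-08). SCD, stearoyl-CoA desaturase, rose from 24.4 ± 7.29 to 107 ± 20.7 FPKM and FASN, fatty acid synthase, from 34.4 ± 4.74 to 64.5 ± 2.70 FPKM, and FADS1 and ELOVL5 were 2.93 and 2.0 times as high. Of 22 cholesterol synthesis genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a camera adjusted p of 5.45e-05 against an adjusted p = 0.518 with an estimated correlation, and 7 rose when no filter on low genes was set. INSIG1, a sterol sensor partner, rose from 29.0 ± 7.47 to 67.3 ± 4.77 FPKM, and ACAT2 and STARD4 were 1.497 and 1.65 times as high. Of 22 fatty acid oxidation genes, 0 rose and 9 fell, the same adjusted over the list alone (median -0.22, camera adjusted p = 0.0101, against an adjusted p = 0.375 with an estimated correlation). CPT1A, the carnitine palmitoyltransferase that sets entry of fatty acids into mitochondria, fell from 37.0 ± 4.88 to 24.2 ± 1.16 FPKM, and ECHS1, CPT2 and SLC25A20 fell to 0.684, 0.675 and 0.674 times the control level.

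Glycolytic and hypoxia-inducible genes rose in the TAZ libraries, where 24 of 33 tested members were higher and 2 lower (25 and 3 adjusted over the list alone). The list's median was 0.54, with a camera adjusted p of 4.84e-11 that held at an adjusted p = 0.0416 with an estimated correlation. SLC2A3, a glucose transporter, rose from 5.44 ± 0.866 to 42.2 ± 5.26 FPKM (log2 fold change 2.75, SE 0.12, limma adjusted p = 8.81e-10). CA12, a carbonic anhydrase, rose from 12.1 ± 1.58 to 72.6 ± 8.85 FPKM, EGLN3, a HIF prolyl hydroxylase, from 1.23 ± 0.171 to 9.07 ± 1.19 FPKM and BNIP3, a mitophagy receptor, from 35.2 ± 1.68 to 109.5 ± 8.10 FPKM, whereas PFKM, muscle phosphofructokinase, fell from 5.55 ± 0.17 to 3.48 ± 0.214 FPKM. Nuclear genes of oxidative phosphorylation were slightly lower, with 0 of 42 that rose and 18 that fell (0 and 21 adjusted over the list alone), at a median of -0.21 and a camera adjusted p of 0.000808, against an adjusted p = 0.535 with an estimated correlation. ATP5G2 fell from 310 ± 18.8 to 225 ± 12.4 FPKM, and NDUFB10, NDUFS7 and NDUFB4, which encode subunits of complex I, fell to 0.705, 0.699 and 0.737 times the control level. The number that fell was 11 under median-ratio scaling, 11 without control replicate 2 and 10 without TAZ replicate 1, and with a trend of the fold change with gene length removed 8 fell and 1 rose. Of 74 cytosolic ribosomal protein genes, 0 rose and 44 fell (0 and 50 adjusted over the list alone), at a median of -0.29 and a camera adjusted p of 3.94e-07, against an adjusted p = 0.568 with an estimated correlation. RPL22, RPS13 and RPS7 fell to 0.728, 0.759 and 0.740 times the control level. The number that fell was 19 under median-ratio scaling, 15 with no filter, 23, 16 and 24 without control replicate 2, TAZ replicate 1 and TAZ replicate 2, and 2 once the length trend was removed, which left adjusted p-values of 0.0595 for the ribosomal list and 0.206 for the oxidative phosphorylation list. Under quantile normalization 30 ribosomal genes fell and 2 rose. Ribosomal protein genes have many processed copies in mammalian genomes, so their counts are uncertain. The mitochondrially encoded transcripts were not analysed here.

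**Figure D3:**
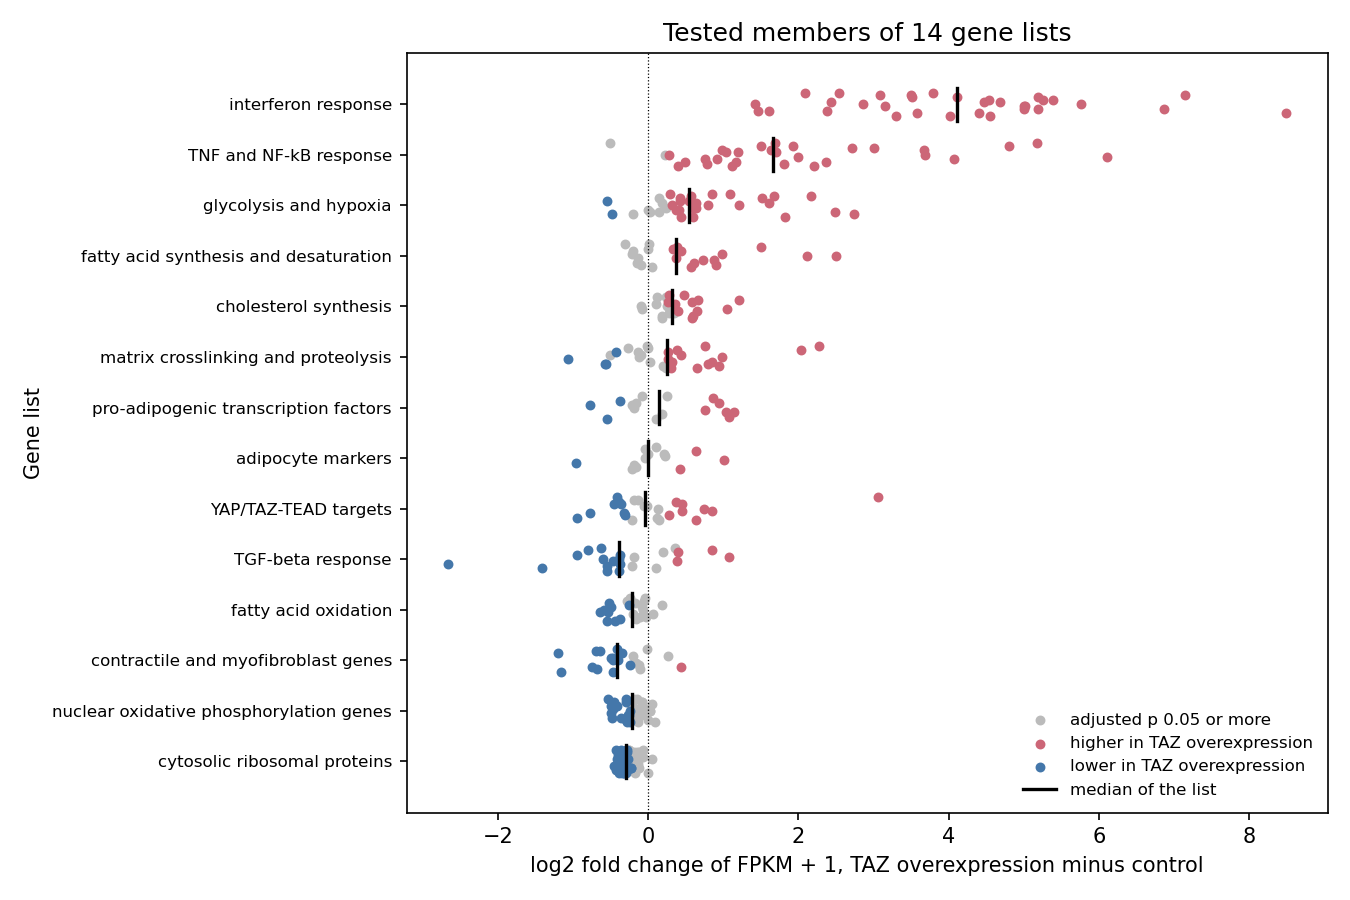
Log2 fold change of FPKM + 1 (horizontal axis, TAZ overexpression minus control) of the tested members of 14 gene lists (vertical axis), 1 point per gene, coloured red or blue where the gene was called higher or lower at an adjusted p under 0.05 and grey otherwise, with a black bar at each list's median. The interferon list lies wholly to the right with a median of 4.12, the YAP/TAZ-TEAD targets spread to both sides around -0.038, and the ribosomal protein genes sit in a narrow band around -0.29, of which 30 fell and 2 rose under quantile normalization.

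Contractile and myofibroblast genes fell, with 1 of 21 tested members higher and 14 lower (1 and 15 adjusted over the list alone). Their median was -0.42 and camera's adjusted p 0.000392, which was lost at an adjusted p = 0.375 with an estimated correlation. ACTA2, smooth muscle actin, fell from 442 ± 113 to 195 ± 39.3 FPKM (log2 fold change -1.17, SE 0.17, limma adjusted p = 0.000148). LMOD1, ITGA8 and CNN2 fell to 0.345, 0.412 and 0.636 times the control level, and CNN1, a calponin, rose to 1.36 times. Of 28 tested genes of matrix crosslinking and proteolysis 14 rose and 4 fell (14 and 5 adjusted over the list alone), with a camera adjusted p of 0.0219 that was lost at an adjusted p = 0.375 with an estimated correlation and at 0.0512 with the stricter filter. The aggrecanase gene ADAMTS5 rose from 0.949 ± 0.131 to 8.46 ± 1.07 FPKM, the collagenase MMP1 from 50.6 ± 18.3 to 201 ± 5.84 FPKM and the lysyl oxidase family member LOXL2 from 152.5 ± 20.6 to 300.1 ± 7.50 FPKM, and MMP11 fell to 0.450 times the control level. The collagen and matrix list had 12 members that rose and 9 that fell of 40 (13 and 9 adjusted over the list alone) and was not called (camera adjusted p = 0.575, direction up, median -0.052, mean 0.062). VCAN, a large proteoglycan, rose from 56.3 ± 11.4 to 218 ± 30.8 FPKM, COL5A3 and COL4A1 were 2.03 and 1.52 times as high, and BGN fell from 383 ± 26.7 to 236 ± 8.57 FPKM.

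Several ligands and regulators of developmental signalling moved. Of 22 tested genes of the TGF-beta response 4 rose and 13 fell (5 and 13 adjusted over the list alone), and the list missed the threshold at a camera adjusted p of 0.06. It passed under median-ratio scaling (0.0384), after rescaling without the top 50 genes (0.034) and with fry (0.00102). Without control replicate 1, TAZ replicate 1 or TAZ replicate 2 it passed as well (0.0394, 0.0431 and 0.0464). The list also passed with camera on ranks (0.0488), with voom (0.0448) and with the length trend removed (0.0345), but not with an estimated correlation (0.375). LTBP3, a latent TGF-beta binding protein gene, fell from 31.8 ± 6.21 to 11.2 ± 0.0290 FPKM (log2 fold change -1.41, SE 0.12, limma adjusted p = 7.78e-07), and LTBP1 rose from 32.5 ± 5.14 to 59.1 ± 4.69 FPKM. Of 22 Wnt signalling genes 3 rose and 7 fell, the same adjusted over the list alone, with a camera adjusted p of 0.578, and 12 fell with no filter and 2 with the stricter one. The Wnt antagonist family member DKK3 fell from 33.8 ± 1.14 to 12.4 ± 1.67 FPKM and the receptor FZD8 from 5.19 ± 0.865 to 1.35 ± 0.0142 FPKM, while RSPO1, which potentiates Wnt signals, rose from 0.940 ± 0.314 to 5.002 ± 0.523 FPKM. Of 9 osteogenic markers 2 rose and 5 fell (3 and 5 adjusted over the list alone), with a camera adjusted p of 0.363. Without control replicate 1, TAZ replicate 1 or TAZ replicate 3, and with no filter, 1 rose, and with the stricter filter 1 rose and 1 fell of 3 tested. OMD, BMP2, SP7 and DLX3 fell to 0.103, 0.272, 0.426 and 0.564 times the control level, and BMP4 was 1.43 times as high. RUNX2, the osteoblast regulator, stood at 8.82 ± 0.954 against 6.94 ± 0.724 FPKM (adjusted p = 0.0387). That call was lost under median-ratio scaling (0.0695), after rescaling without the top 50 genes (0.106), with no filter (0.0847) and without control replicates 2 or 3 or TAZ replicates 2 or 3 (0.0606, 0.111, 0.152 and 0.0844). The chondrogenic markers had 1 tested member, SOX9, which fell from 2.96 ± 0.688 to 1.61 ± 0.245 FPKM.

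Markers of mesenchymal stromal cells were present in both groups, and 7 of 16 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.161). The 5 falls became 3 without control replicate 1 and 2 without TAZ replicate 2. ALCAM, a cell adhesion molecule, rose from 26.3 ± 4.04 to 110.4 ± 8.63 FPKM (log2 fold change 2.04, SE 0.11, limma adjusted p = 9.88e-09), PDGFRB, a growth factor receptor, was 1.72 times as high and ENG, a TGF-beta co-receptor, fell to 0.619 times the control level. Of 38 genes of the G2/M list 3 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.575), and of 41 of DNA replication and S phase 5 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.302). Over all tested genes 37.9% changed, a larger share than in either list. The G2/M genes that rose numbered 0, 5, 0 and 1 without control replicate 2, control replicate 3, TAZ replicate 1 and TAZ replicate 2, and 5 under median-ratio scaling or with the length trend removed, and 1 fell without control replicate 2 or 3. The S phase genes that rose numbered 1, 3 and 1 without control replicate 2, TAZ replicate 1 and TAZ replicate 2, 8 under median-ratio scaling and 2 with no filter, and those that fell 2 without control replicate 2 or 3 and 0 without control replicate 1, TAZ replicate 2 or TAZ replicate 3. The S phase list was called up without control replicate 1 (adjusted p = 0.0385), but not over all libraries with an estimated correlation (adjusted p = 0.809). E2F2, an S phase regulator, rose from 0.361 ± 0.116 to 1.51 ± 0.186 FPKM (log2 fold change 0.88). POLA1 and POLD1 were 1.39 and 1.25 times as high, and CCNE2 fell to 0.713 times the control level. The calls of POLA1, POLD1 and CCNE2 were lost, among other settings, without TAZ replicate 2 (limma adjusted p = 0.0601, 0.095 and 0.0687). They were also lost with no filter (0.0541, 0.0588 and 0.0689). CDK1, CCNA2 and ECT2 were 1.30, 1.24 and 1.37 times as high, and each of these 3 calls was lost without control replicate 2 (adjusted p = 0.0754, 0.106 and 0.0958) or without TAZ replicate 1 (0.0554, 0.0519 and 0.0621). Leaving out control replicate 1 or TAZ replicate 2 also ended the call of ECT2 (0.0552 and 0.0533), and leaving out TAZ replicate 2 that of CCNA2 (0.0616).

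Stress-related lists were not called by camera, and all but the heat shock list had members on both sides. Of 22 genes of the p53 response and senescence 9 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.186), with BTG2, FAS and MDM2 at 2.004, 2.02 and 1.53 times the control level and TP53INP1 at 0.651 times. The 5 falls became 2 without control replicate 1, TAZ replicate 1 or TAZ replicate 2, 3 without control replicate 2 or TAZ replicate 3, and 1 with no filter. Of 31 genes of the unfolded protein and stress response 10 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.266), and 5, 6 and 6 rose without control replicate 1, without TAZ replicate 1 and with no filter. DDIT4, an inhibitor of mTORC1, rose from 21.5 ± 4.83 to 101.7 ± 18.5 FPKM (log2 fold change 2.20, SE 0.15, limma adjusted p = 8.88e-08), VEGFA was 1.52 times as high and ASNS, asparagine synthetase, fell to 0.525 times the control level. Of 17 heat shock genes 4 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.266), with HSPB8 2.54 times and DNAJA1 1.58 times as high. HSPA8 and DNAJB4 were 1.23 and 1.32 times as high. The call of HSPA8 was lost with the replicate number as a block (limma adjusted p = 0.0509). That of DNAJB4 was lost without control replicate 1 or 2, without TAZ replicate 1 and with no filter (0.123, 0.0556, 0.117 and 0.0904). Of 22 immediate early genes 6 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.302), with NR4A2 2.68 times as high and KLF2 and EGR3 at 0.506 and 0.373 times the control level. That share of called members was close to the 37.9% over all tested genes.

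Markers of other cell types were mostly near 0. PTPRC, the pan-leukocyte marker, had 0 fragments in each library, and the median over 16 measured leukocyte markers was 0.125 FPKM in the controls and 0.0287 FPKM in the TAZ libraries. Among the 4 tested leukocyte markers, CD14, a co-receptor for bacterial lipopolysaccharide, rose from 9.58 ± 1.38 to 24.2 ± 0.421 FPKM and LAPTM5 from 9.47 ± 0.228 to 13.3 ± 0.761 FPKM, whereas CORO1A and CD68 fell from 6.66 ± 0.793 to 2.99 ± 0.350 FPKM and from 4.53 ± 0.437 to 2.86 ± 0.333 FPKM. The endothelial list had a median of 0.0178 FPKM in the controls and 0.0233 FPKM in the TAZ libraries over 14 measured genes, and of its 3 tested members FLT1 rose (0.509 ± 0.154 to 1.51 ± 0.133 FPKM), ERG fell (10.1 ± 0.525 to 5.77 ± 0.311 FPKM) and EGFL7 did not pass (18.3 ± 3.53 against 13.8 ± 2.41 FPKM). EGFL7 fell past the threshold without control replicate 3 or TAZ replicate 3 (limma adjusted p = 0.00401 and 0.0229). Of 4 tested pericyte markers, PDGFRB, NOTCH3 and ANGPT1 rose, the last of these not without control replicates 1 or 2 or TAZ replicate 1 (adjusted p = 0.1, 0.0906 and 0.0903), and CSPG4 stood at 25.7 ± 4.56 against 25.6 ± 5.58 FPKM. MSLN, the 1 tested epithelial and mesothelial marker, fell from 1.52 ± 0.227 to 0.518 ± 0.0715 FPKM, and TNNI1, the 1 tested skeletal muscle marker, fell from 4.62 ± 0.566 to 2.96 ± 0.237 FPKM.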

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

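The tests of construct delivery, of targets moving in both directions and of dilution, and the repeat of all tests without the length trend, were chosen only after the results they bear on were seen. In 23 rows of the tables a date stood where a gene symbol would be, and these rows entered no comparison. Of them 17 passed the expression filter, and 4 were higher and 4 lower in the TAZ libraries at a limma adjusted p under 0.05. They drew attention as a signal in data that the report leaves out.

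The first pattern weighed is the joint rise of interferon and NF-kB response genes, 33 of 33 and 28 of 30. Leukocytes in the TAZ cultures are argued against, since the median of 16 leukocyte markers was 0.0287 FPKM there and PTPRC had 0 fragments in each library, although CD14 and LAPTM5 rose. Scaling of the libraries is argued against by the size of the rise, since the interferon median was 4.12 where that of all tested genes was -0.0501. The 3 other scalings could hardly decide this, since they left the median of all tested genes between -0.0616 and -0.00436. Under each of them 100% of the interferon members rose. Of the 30 NF-kB members 28, 27 and 28 rose under median-ratio scaling, quantile normalization and rescaling without the top 50 genes. What may stay open is a response to delivery of the construct itself, which cannot be told apart from one to TAZ because 0 control libraries are labelled as carrying an empty construct. Whether the groups differed in exposure to TNF-α, which the study's title names, cannot be told either, since no label mentions a cytokine treatment. The design's own explanation, the higher TAZ level, also stays open as untested.

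The second pattern is the lack of a shift of the YAP/TAZ-TEAD target list while WWTR1 was 2.99 times as high. Too little depth to call single members is argued against, since 98.1% of simulated 1.5-fold changes of the 24 tested members were recovered over 20 draws. The simulation gave every gene the same spread between replicates, so noisier members may be recovered less often. It counted calls of single members and so does not say whether camera would have called the list. Of the 24 members 8 were higher and 8 lower, where 37.9% of all 10750 tested genes changed, 1693 higher and 2381 lower. Members were thus called more often than genes in general in both directions, a difference that was not tested. Fry's mixed test in limma gave an adjusted p = 8.73e-06 over the lists (2.91e-06 unadjusted). It was under 0.05 for 26 of the 27 tested lists, and so decides nothing about this one. The amount and location of TAZ protein were not analysed here.

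The third pattern is the small fall of ribosomal protein and oxidative phosphorylation genes. Dilution by the induced genes is argued against, since the median log2 fold change of all tested genes was -0.0501 against -0.293 for the ribosomal list. A trend with gene length may account for much of it. Fold changes rose with recovered length across genes (Spearman rho 0.164, genes not being independent replicates), and 705 other genes about as short as the ribosomal ones, whose median length was 719 bases, had a median of -0.177. With the level and trend of the other genes taken off, the ribosomal median was -0.0756 (SD over members 0.105) and the oxidative phosphorylation median -0.0335. With a trend over all genes removed and the overall level kept, the ribosomal median moved from -0.293 (SD 0.103) to -0.118 (SD 0.106) and the oxidative phosphorylation median from -0.214 (SD 0.163) to -0.0705 (SD 0.168), where the median of all tested genes was -0.0378. Both camera calls ended there (adjusted p = 0.0595 and 0.206), where the folds shrank and the SDs over members hardly moved. Which part of the test ended the calls was not examined, and a small ribosomal fall stays unexplained.

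The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes changed, 1 of the 10 splits, the real one, gave as many as its 4074, and the highest of the others gave 0 by limma, where between 7 and 586 genes had an unadjusted p under 0.05 against 5020 in the real split. For genes changed at least 2-fold, 1 of 10 gave as many as the real 486, and the highest of the others gave 0. For lists called by camera at its preset correlation, 4 of 10 splits gave as many as the real 10, and the highest of the others gave 13.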

How the results depend on the processing

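The voom fit on recovered fragments and the removal of the length trend were chosen after the data were seen. Over all settings 130 counts of genes past a threshold or lists called stayed within 1.5 times of their value and 11 did not (counts within single lists stand in the report), and 0 named genes or single lists changed direction past a threshold. The balance of higher and lower genes did turn, with 2001 higher and 1821 lower under median-ratio scaling, and also in the treat test. Genes at least 2-fold lower numbered 231 with a pseudocount of 0.1, 66 with the stricter filter, which tests fewer genes, and 252 with voom, which adds less to low values, and voom gave 756 genes changed at least 2-fold. An adjusted p under 0.01 left 2612 genes changed, 1408 of them lower, and the treat test against 1.2-fold left 1379, with 781 higher and 598 lower, by construction. Leaving out each library gave 3205 to 4396 changed genes, 3113 to 3768 of them among the 4074, with 0 changes of sign. The 486 genes changed at least 2-fold over all libraries were each still called as changed. Whether each of them stayed at least 2-fold was not tested.

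Camera with an estimated correlation called 2 lists and fry 19, in place of 10. Fry, which does not compare a list with other genes, added lists on both sides. It called up the pro-adipogenic factors (fry adjusted p = 0.01), adipocyte markers (0.0497), TNF receptor components (0.0115), stromal markers (0.00289), p53 response (0.016) and heat shock (0.0173). It called down the anti-adipogenic factors (0.00735) and the TGF-beta (0.00102), Wnt (0.0198) and osteogenic (0.016) lists. With an estimated correlation the adjusted p was 0.375 for fatty acid synthesis, fatty acid oxidation, matrix crosslinking and contractile genes, 0.518 for cholesterol synthesis, 0.202 for the NF-kB response, 0.535 for oxidative phosphorylation and 0.568 for ribosomal proteins. The estimates for these lists ran from 0.0226 for matrix crosslinking to 0.817 for ribosomal proteins, against the preset 0.01. Members varying together cannot account for every higher p. The TGF-beta list, with an estimate of -0.0244, also went from an unadjusted camera p of 0.0245 to 0.0686. Matrix crosslinking, with an estimate of only 0.0226, went from an unadjusted camera p of 0.00811 to 0.0783. A call lost in this setting is thus by itself no sign that members varied together. Ribosomal proteins also missed the threshold with fry (0.0655), which compares with no other genes, and the cause was not tested. Removing the length trend left 0.206 for oxidative phosphorylation and 0.0595 for ribosomal proteins, and the stricter filter 0.0512 for matrix crosslinking, which tests fewer genes. Of 138 called named genes, 122 kept call and direction under every setting that tested them and 16 lost the call under at least 1.

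Same-numbered libraries did not deviate together (correlations of deviations from the group means -0.436, -0.112 and -0.403), and no library correlated best with its own number (the highest values were 0.691 for control replicate 3 with TAZ replicate 1, 0.552 for 2 with 3 and 0.534 for 1 with 2), so the labels give only a shared number. Control replicate 3 and TAZ replicate 1 also stood apart on the second principal component, at -13.09 and -10.3 against 3.88 to 7.57 for the others. That component held 7% of the variance. A batch or a pairing under other numbers is thus possible, but no label names one and none was modelled. A replicate block called 3512 genes, 1548 higher and 1964 lower, with adjusted p-values of 0.0962 for fatty acid oxidation, 0.0528 for matrix crosslinking and 0.0501 for oxidative phosphorylation, and it called the TGF-beta response and stromal marker lists (0.0271 each, against 0.375 and 0.423 with an estimated correlation). It ended the calls of TNFRSF1A (0.115) and RUNX2 (0.0633) and called EGFL7 (0.0142). Depth limited genes under 1 FPKM, such as PPARG with 9 and 14 fragments. Of changes of 1.5-fold, 86.6% were recovered in simulated data, which did not separate depth from the spread between replicates.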

Other observations

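These gene groups were chosen after the values had been seen, so their tests are no independent evidence. Genes that prepare peptides for MHC class I rose, 13 of 15 tested, with 1 that fell and 1 that did not pass (median log2 fold change 1.62, camera adjusted p = 3.66e-13 over these groups, adjusted p = 0.0106 with an estimated correlation), and 3 of the 15 are also in the interferon list. PSMB9, an immunoproteasome subunit gene, went from 0.810 ± 0.252 to 41.0 ± 4.79 FPKM (SD, n = 3 in each group), and the peptide transporter gene TAP1 from 4.43 ± 0.652 to 45.1 ± 3.80 FPKM, while CALR, the chaperone calreticulin, fell to 0.740 times the control level. Of 8 tested complement genes 7 rose and 1 did not pass (camera adjusted p = 4e-08, adjusted p = 0.0705 with an estimated correlation). C3, the central complement component, was 9.96 times as high and CFB, which forms the alternative pathway convertase with it, went from 0.177 ± 0.0523 to 10.5 ± 0.974 FPKM.

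Small leucine-rich proteoglycan genes split, with 6 of 10 that fell, 2 that rose and 2 that did not pass (camera adjusted p = 0.0229, adjusted p = 0.352 with an estimated correlation). ASPN, OGN and OMD fell to 0.15, 0.184 and 0.103 times the control level, whereas DCN, which encodes decorin, rose from 1430 ± 122 to 2188 ± 271 FPKM. Genes of the BMP response also split, with 7 of 13 lower and 3 higher, and were not called (camera adjusted p = 0.0672, adjusted p = 0.369 with an estimated correlation). ATOH8, a BMP-responsive transcription factor gene, fell from 3.44 ± 0.800 to 0.205 ± 0.0525 FPKM, and ID4 was 2.76 times as high while ID1 fell to 0.155 times the control level. EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha, rose from 53.8 ± 10.1 to 154 ± 17.6 FPKM (log2 fold change 1.51, SE 0.12, limma adjusted p = 6.47e-07).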
